A study of Mus musculus with 8 samples.

How the data were processed

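RNA from gastrocnemius muscle of mice lacking the histone deacetylase Hdac5 and of wild type littermates was hybridised to 8 Affymetrix mouse gene arrays, 4 per genotype. Per the labels, the animals were 30 weeks old and fed a low-fat chow diet, only RNA with an integrity number above 8 was used, and 150 ng of total RNA was amplified and biotin-labelled for each array. The samples were grouped by the genotype given in the labels.

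The deposited values are on a log2 scale, 1 value per probe set and array, and per the submitters' processing notes the authors made them with Affymetrix Expression Console version 4.0. The background correction, the summarisation and the normalization method are not given in the sources used here, and the log2 scale itself was read from the values. The array medians lay between 7.69 and 7.77, and the array maxima between 14.80 and 14.84. The quartiles differed slightly from array to array, so the columns do not share 1 distribution. No filter on dim probe sets had been applied. A probe set whose signal lies near the background gives a compressed change, and the number of arrays sets the precision of every comparison.

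Of the 35556 probe sets in the table, 21789 had exactly 1 gene symbol in the platform annotation, 1621 had several, and 12146 were not listed there. Of the named probe sets, 21698 had an Entrez identifier in the RefSeq gene table of assembly GRCm38.p6, through which 0 symbols needed an update. That table also gave the order of genes along chromosomes. It was used for gene names and gene order alone, because the build behind the array annotation is not given in the sources used here. For the 999 genes with more than 1 probe set, the probe set with the highest mean over the 8 arrays was taken, which left 19938 genes. Probe sets with several symbols or none were kept out of the gene comparison and are treated as a separate observation.

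The deposited log2 values were not normalized again. Knockout and wild type were compared gene by gene with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method over the 19938 genes, and a gene was said to change at an adjusted p under 0.05. Changes are knockout minus wild type, and SE is limma's moderated standard error. Hdac5 and Il6 were also compared by an exact 2-sided permutation test over all arrangements of the 8 arrays, whose smallest possible p is 0.0286. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

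Before the data were examined, 29 gene lists were written from textbook knowledge, along with a further list of sex-linked genes kept outside that family. Of the 762 list entries, 700 were among the tested genes. They cover the IL-6 cytokine family with its receptors and JAK-STAT signalling, IL-6 and STAT3 induced genes, NF-kB and inflammatory cytokine genes, histone deacetylases and their corepressors, MEF2 factors and their muscle target genes, insulin signalling and glucose uptake, glycogen and glycolysis, fatty acid oxidation, the respiratory chain and citrate cycle, and mitochondrial biogenesis. They also cover slow fibre genes, fast fibre genes, myokines, denervation and neuromuscular junction genes, protein breakdown and autophagy, immediate early genes, heat shock and the unfolded protein response, circadian clock genes and the interferon response. The remaining lists hold markers of macrophages, lymphocytes and neutrophils, adipocytes, endothelial cells, fibroblasts and extracellular matrix, tendon, smooth muscle and pericytes, Schwann cells, satellite cells and red blood cells. Each list was compared with all other genes by camera in limma with a preset inter-gene correlation of 0.01, adjusted over the 29 lists. The same test with the correlation estimated from the residuals, and fry, were run beside it. Members were also adjusted over their list alone.

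The rule for the genes named in the text was set at the same time. It takes Hdac5, Il6, and the 12 largest rises and 12 largest falls past the threshold. Where fewer passed, each direction was filled to 12 with the smallest p-values among genes with a log2 change of at least 0.5 in size and a mean above the median gene. From each list it takes up to 4 members of smallest p, and the 2 brightest for cell type lists. As applied, 4 members of smallest p were named in lists that camera called and 2 in the others, so that number followed the result. Gene models without an assigned name were counted and not named.

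Because gene targeting can leave a stretch of donor-strain chromosome around the targeted gene, the 100 tested genes on each side of Hdac5 were compared with all others by Fisher's exact test, counting genes at an unadjusted p under 0.01. The gene and list tests were tested on simulated data with the means and residual spread of the 19938 genes and 200 changed genes, in 10 simulations. With 4 arrays per group the gene test recovered 86.8% of changes of 0.5, 98.8% of changes of 1, 99.8% of changes of 1.5 and 100% of changes of 2 on the log2 scale. It called on average 11.9 unchanged genes. The 1 list shifted in each simulation was called in all 10, with on average 0.1 other lists called. These rates hold for 200 changed genes and noise that was independent between genes. With fewer changed genes the adjusted threshold is stricter, and real list members vary together, so the rates do not carry over to these samples.

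The alternatives tried were keeping only genes above the 30th percentile of the array on at least 4 of the 8 arrays, quantile normalization, median centring, a trended and robust eBayes, array weights, the mean of a gene's probe sets, all probe sets, the replicate number as a block, the first residual principal component as a covariate, no moderation, other thresholds, and each array left out in turn. Sex was not added as a covariate because all 8 arrays showed the same sex-linked pattern. No scanner files were used here.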

Results

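Gene expression in gastrocnemius, a mixed calf muscle of mainly fast fibres, was profiled in 4 Hdac5 knockout samples and 4 samples from wild type littermates. HDAC5 is a class IIa histone deacetylase that represses MEF2-dependent transcription in muscle. The submitters asked what part it plays in the transcription of interleukin 6 (Il6), a cytokine released by working muscle, and of genes that IL-6 regulates. The labels number the samples but do not state that each came from a different animal, so the p-values measure the spread between these samples. Arrays correlated with each other at 0.988 to 0.995 over all probe sets, and no pair held identical values. The median standard deviation of a gene was 0.096 within the knockout group and 0.094 within the wild type group on the log2 scale.

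The targeted gene was lower in each of the 4 knockout samples. Hdac5 fell by 1.497 on the log2 scale (SE 0.059), from 9.83 ± 0.08 (SD, n = 4) in wild type to 8.33 ± 0.04 (SD, n = 4) in knockout muscle, with a limma adjusted p of 1.74e-07. The knockout signal was 0.354 of the wild type signal (95% interval 0.324 to 0.387). The exact permutation p was 0.0286, the smallest that 4 against 4 samples can give. The part of the gene that was deleted is not given in the sources used here, so the remaining signal does not measure functional transcript.

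Il6 showed no detectable difference. Its level was 4.87 ± 0.11 (SD, n = 4) in knockout and 4.80 ± 0.15 (SD, n = 4) in wild type muscle, a difference of 0.07 (SE 0.083) with an exact permutation p of 0.514 and a limma adjusted p of 0.892. The 95% interval of the difference ran from -0.11 to 0.25. Il6 lay at the 2.67th percentile of gene signals, near the floor of the arrays, where changes are compressed, so a difference in the transcript could go unseen. The plot of single samples shows Il6 beside the genes that passed the threshold.

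Genes of the IL-6 pathway did not shift as a group. None of the 24 measured members of the IL-6 cytokine, receptor and JAK-STAT list passed over all genes, and 1 fell when adjusted over the list alone: Cntfr, the ciliary neurotrophic factor receptor, at 9.76 against 10.29 (difference -0.53, SE 0.123, adjusted p = 0.0255 over the list alone and 0.198 over all genes in limma). Lifr, the leukaemia inhibitory factor receptor, differed by 0.15 (unadjusted p = 0.0301 in limma). The list's median change was 0.02, its mean -0.03 and its camera direction downward (adjusted p = 0.932). Without wild type sample 3 the mean was -0.0068 and without knockout sample 1 it was -0.017, each with an upward camera direction (adjusted p = 0.880 and 0.966). Of the 34 IL-6 and STAT3 induced genes, 0 passed over all genes and 0 when adjusted over the list alone, and the list had a mean change of 0.0056 (camera adjusted p = 0.920), with a sign that turned without knockout sample 3 (-0.0075), knockout sample 4 (-0.00055) or wild type sample 3 (-0.0087). With dim probe sets left out the mean of that list was 0.029 (camera adjusted p = 0.561), so its dim members weigh on the mean. The members with the smallest p were Fos, an immediate early transcription factor, at a difference of 0.27 (SE 0.094), and Lrg1, a secreted glycoprotein, at 0.19 (SE 0.073). At an unadjusted p under 0.05 in limma, 4 of these genes were higher and 1 was lower. The NF-kB and inflammatory cytokine list (25 genes) had a mean change of 0.0097 (camera adjusted p = 0.922), 0 members passed over all genes or when adjusted over the list alone, and Cxcl10 differed by -0.14 and Il18 by 0.13. Its mean was 0.00031 without knockout sample 4, 0.0019 without wild type sample 3 and 0.017 without knockout sample 2.

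Beyond Hdac5, few transcripts separated the genotypes. In limma, 13 of the 19938 genes changed, 8 upward and 5 downward. Prm1, the protamine that packs DNA in sperm heads, rose by 1.97 (SE 0.081, adjusted p = 1.74e-07), 3.93-fold, from 7.67 ± 0.14 to 9.65 ± 0.11 (SD, n = 4 each). Htra4, a secreted serine protease, fell by 1.57 (SE 0.095, adjusted p = 1.00e-05). Dusp26, a protein phosphatase, fell by 0.92 (SE 0.107, adjusted p = 0.00753), and Efr3b, part of a lipid kinase complex at the plasma membrane, rose by 0.55 (SE 0.062, adjusted p = 0.00753). In each of the 13 genes every knockout sample lay beyond every wild type sample. That held for 4.90% of all genes, where chance gives 2.86%.

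The other 8 changed genes had adjusted p-values between 0.0240 and 0.0447 in limma. Utp18, which takes part in ribosomal RNA processing, rose by 0.97 (SE 0.143), the hydrolase Cmbl by 0.82 (SE 0.108) and the complement component C7 by 0.71 (SE 0.102). Spinkl, a Kazal-type protease inhibitor, rose by 0.55 (SE 0.080), the lipid transporter Abca5 by 0.51 (SE 0.078) and Ramp1, a subunit of the receptor for calcitonin gene-related peptide, by 0.43 (SE 0.063). H60b, a ligand of the natural killer cell receptor NKG2D, fell by 0.74 (SE 0.110), and Bckdhb, a subunit of the enzyme that commits branched-chain amino acids to oxidation, fell by 0.42 (SE 0.064).

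**Figure D1:**
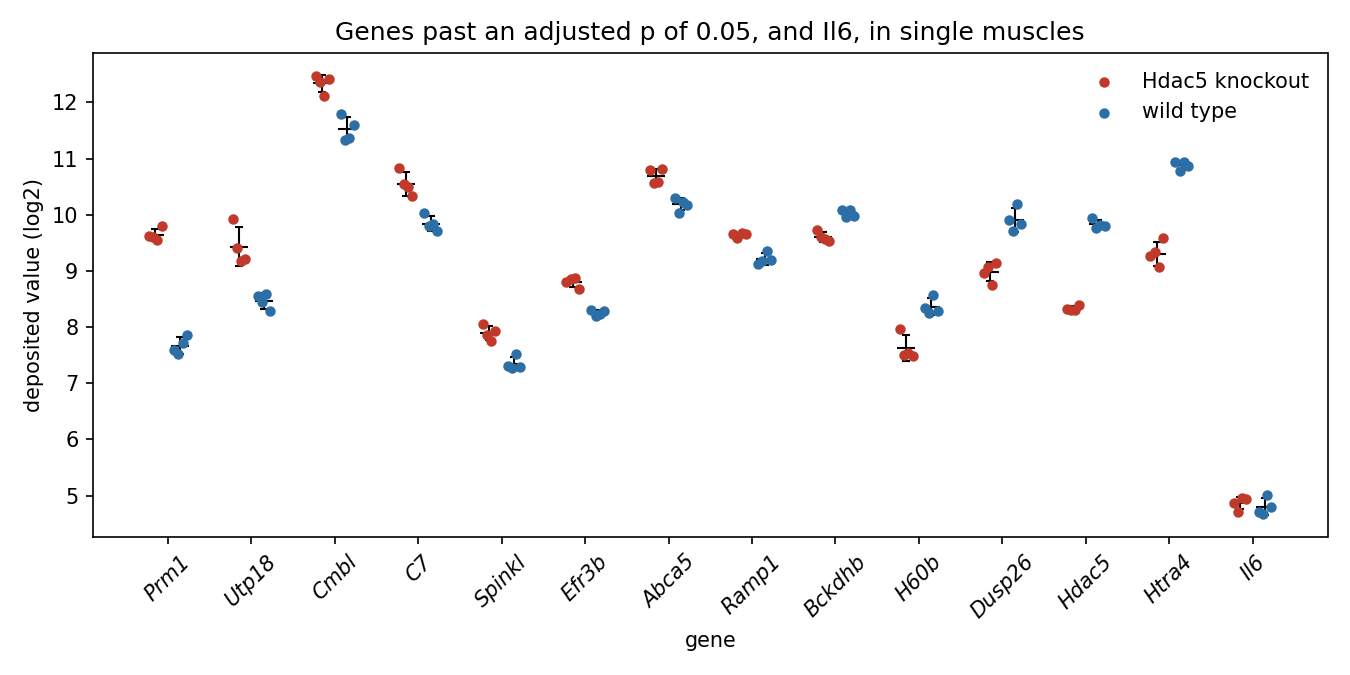
Deposited log2 value (vertical axis) of each gene that changed, and of Il6, in the 4 Hdac5 knockout samples (red) and the 4 wild type samples (blue); black bars give the mean and SD of each group. The groups do not overlap for the 13 changed genes, with Prm1 at 9.65 against 7.67 and Hdac5 at 8.33 against 9.83, and they overlap for Il6.

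With any 1 sample left out, Hdac5, Prm1, Htra4, Dusp26 and Efr3b passed each time, while Abca5 passed in 0 of the 8 fits, H60b, Bckdhb and Ramp1 in 1 each, C7 and Spinkl in 2, and Cmbl and Utp18 in 3. The number of changed genes was 5 without wild type sample 2 or wild type sample 4, 7 without knockout sample 2, 8 without knockout sample 1 or wild type sample 1, and 20 without knockout sample 4. It was also 5 without both knockout sample 1 and wild type sample 4, the arrays at opposite ends of the first principal component, an alternative chosen after seeing the data.

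Bright genes that did not pass were named by the rule that filled each direction, and not all of them came close to the threshold. Higher in knockout muscle were Lynx1 (difference 0.78, SE 0.153), Klf10 (0.72, SE 0.133), Dph6 (0.64, SE 0.115) and Snai3 (0.61, SE 0.104), with limma adjusted p-values of 0.117, 0.0797, 0.0763 and 0.0739. Lower were Lrrn1 (-0.63, SE 0.128), Ctxn3 (-0.59, SE 0.118) and Aebp1 (-0.54, SE 0.089), with adjusted p-values of 0.130, 0.126 and 0.0628, together with Tnnc1, Myl3 and Tnni1 of the slow fibre programme. Ankrd33b differed by -0.60 on its brightest probe set (adjusted p = 0.0968), but its other probe sets gave -0.01, 0.14 and -0.23. In all, 46 genes had an adjusted p under 0.1, and 1576 genes (7.90%) had an unadjusted p under 0.05 in limma, where chance gives 996.9.

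Slow fibre genes had a lower mean in knockout muscle, although the score of knockout sample 3 (11.14) lay just above that of wild type sample 1 (11.13). Of the 21 measured, 10 fell and 1 rose when adjusted over the list alone, and 0 passed over all genes. Myh7, the slow myosin heavy chain, fell by 0.76 (SE 0.199, 11.72 against 12.48), the slow troponins Tnnc1 by 0.76 (SE 0.132) and Tnni1 by 0.71 (SE 0.158), and the slow myosin light chain Myl3 by 0.61 (SE 0.125), with adjusted p-values over the list alone of 0.0128, 0.00210, 0.00507 and 0.00392 and over all genes of 0.266, 0.0763, 0.176 and 0.130 in limma. The list's mean change was -0.23 and its median -0.11 (camera adjusted p = 1.48e-06), but adjusted p = 0.584 with an estimated correlation, since the members vary together. Markers of tendon and of Schwann cells also had lower means in knockout muscle, with mean changes of -0.14 and -0.12, although single samples of the genotypes overlapped.

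Fast fibre genes did not move the other way. Of 24, 1 rose when adjusted over the list alone and 0 over all genes: Kcng4, a potassium channel subunit, by 0.46 (SE 0.080, adjusted p = 0.00257 over the list alone and 0.0763 over all genes in limma). Mylk2, the skeletal myosin light chain kinase, differed by 0.10 (SE 0.054). The list's mean change was 0.0067, its median -0.018 and its camera direction downward (adjusted p = 0.845).

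Myokines, the proteins that muscle secretes, had a higher mean in knockout muscle, although the score of wild type sample 2 (9.11, against 9.01 to 9.02 in the other wild type samples) lay just above that of knockout sample 2 (9.10). Of 26, 3 rose when adjusted over the list alone and 0 over all genes: Il15, a cytokine abundant in muscle, by 0.47 (SE 0.101), the growth factor Igf1 by 0.36 (SE 0.095) and Mstn, the inhibitor of muscle growth, by 0.27 (SE 0.074), with limma adjusted p-values over the list alone of 0.0158, 0.0300 and 0.0300 and over all genes of 0.160, 0.275 and 0.309. Fstl1, a secreted glycoprotein, differed by 0.33 (SE 0.110, adjusted p = 0.0789 over the list alone). The list's mean change was 0.10 and its median 0.05 (camera adjusted p = 0.00307; adjusted p = 0.490 with an estimated correlation). Macrophage and fibroblast markers also had higher means in knockout muscle, by 0.19 and 0.17, although single samples of the genotypes overlapped. The myokine list shares Dcn and Sparc with the fibroblast list, so their shifts are not separate evidence. Which cells of the muscle made the myokine transcripts was not tested.

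MEF2 factors and MEF2 target genes, the best known targets of class IIa deacetylases in muscle, had a slightly higher mean, although the score of wild type sample 3 (11.76) lay above that of knockout sample 4 (11.73). Of 36, 2 rose and 1 fell when adjusted over the list alone, and 0 passed over all genes. Hdac9, another class IIa deacetylase and itself a MEF2 target, rose by 0.37 (SE 0.079), and Klhl40, a stabiliser of thin filament proteins, rose by 0.25 (SE 0.062). Tnnc1 of the slow fibre programme fell by 0.76. Their adjusted p-values in limma were 0.0114, 0.0219 and 0.00359 over the list alone and 0.163, 0.248 and 0.0763 over all genes. Lrrc39, a sarcomeric protein, differed by 0.22 (SE 0.067, adjusted p = 0.0569 over the list alone). The list had a mean change of 0.06 (camera adjusted p = 0.00699; adjusted p = 0.490 with an estimated correlation). Without both knockout sample 1 and wild type sample 4, an alternative chosen after seeing the data, the mean was 0.04 (adjusted p = 0.0925).

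Of the 20 other deacetylase and corepressor genes measured, Hdac9 alone rose when adjusted over the list alone (adjusted p = 0.0126 in limma) and 0 passed over all genes. Hdac1 differed by 0.16 (SE 0.058) on its brightest probe set and by 0.09 on the other. The list had a mean change of 0.05 (camera adjusted p = 0.187). It was 0.031 without knockout sample 1, 0.017 without wild type sample 4, and 0.0015 with a downward camera direction without both, the last chosen after seeing the data.

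Insulin signalling and glucose uptake genes went both ways. Of 32, 3 rose and 2 fell when adjusted over the list alone, and 0 passed over all genes. Tbc1d4, the Akt substrate that controls glucose transporter traffic, rose by 0.37 (SE 0.070, adjusted p = 0.00642 over the list alone and 0.0930 over all genes in limma), and Igf1 rose by 0.36 (adjusted p = 0.0415 over the list alone). The mean change of the list was 0.018 (camera adjusted p = 0.920). It was 0.00013 without wild type sample 4, 0.011 without knockout sample 2 and 0.031 without wild type sample 1.

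Energy metabolism lists did not pass with all 8 samples. Of 39 respiratory chain and citrate cycle genes, 1 fell when adjusted over the list alone and 0 over all genes: Cox6a2, the muscle form of a cytochrome c oxidase subunit, by 0.33 (SE 0.060, adjusted p = 0.00519 over the list alone and 0.0763 over all genes in limma). Cox8b, another subunit of that enzyme, differed by -0.19 (SE 0.053), and the list's mean change was -0.03 (camera adjusted p = 0.0643). That list passed downward in 7 of 19 alternatives, with camera adjusted p-values of 0.00840 with a trended and robust eBayes, 0.0282 with dim probe sets left out, 0.0485 without both knockout sample 1 and wild type sample 4 (chosen after seeing the data), and 0.0284, 0.0349, 0.0336 and 0.0296 without knockout sample 2, knockout sample 3, wild type sample 2 and wild type sample 4. It did not pass with an estimated correlation (adjusted p = 0.644) or by fry (adjusted p = 0.366). Glycogen and glycolysis genes had a mean change of 0.06 (25 genes, camera adjusted p = 0.142), with Fbp2, a gluconeogenic bisphosphatase, at a difference of 0.60 (SE 0.165) and the glycolytic kinase Pgk1 at 0.15 (SE 0.050). Fatty acid oxidation genes had a mean change of 0.05 (33 genes, camera adjusted p = 0.15), with the mitochondrial carrier Ucp3 at 0.54 (SE 0.184) and Echs1, an enoyl-CoA hydratase, at -0.22 (SE 0.058). Mitochondrial biogenesis regulators had a mean change of -0.012 and a median of 0.0090 (17 genes, camera direction downward, adjusted p = 0.812), with Esrrg at -0.18 and Nrip1 at -0.19. The glycolysis list passed upward without knockout sample 4 (camera adjusted p = 0.0157), without wild type sample 4 (0.0383) and with array weights (0.04997), and the fatty acid list without knockout sample 1 (0.0115) and without knockout sample 4 (0.0424). With an estimated correlation both had an adjusted p of 0.884. The glycolysis mean was 0.038 without knockout sample 1, and the fatty acid mean was 0.031 without knockout sample 2 and 0.032 without wild type sample 4. In the glycolysis, fatty acid and biogenesis lists 0 members passed over all genes or when adjusted over the list alone.

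Markers of macrophages and of fibroblasts with their matrix had higher means, and those of tendon and Schwann cells lower means, in knockout muscle, but the samples of the genotypes overlapped. The macrophage score (the mean of the markers) was 8.46 and 8.51 in knockout samples 1 and 3 and 8.18 and 8.27 in knockout samples 2 and 4, and wild type sample 2, at 8.38, lay above the latter pair. Its fibroblast score of 9.98 likewise lay above those of knockout samples 2 and 4 (9.83 and 9.97). Of 26 macrophage markers, 9 rose when adjusted over the list alone and 0 over all genes. The lysozyme Lyz2 rose by 0.51 (SE 0.134, 10.43 against 9.92), Lyve1 by 0.50 (SE 0.114), Adgre1, which encodes F4/80, by 0.40 (SE 0.105), and Cd68 by 0.32 (SE 0.091), while Cd74, an abundant antigen presentation gene, differed by 0.015 (SE 0.188), a sign that turned under quantile normalization (-0.018). The macrophage list had a mean change of 0.19 (camera adjusted p = 2.15e-08; adjusted p = 0.644 with an estimated correlation). Of 26 fibroblast and matrix genes, 25 had a higher mean in knockout, 0 passed over all genes and 0 when adjusted over the list alone. Its examples were the collagen Col3a1 (difference 0.44, SE 0.111), fibronectin Fn1 (0.42, SE 0.137), Tnxb (0.26, SE 0.080) and Loxl1 (0.24, SE 0.074), and the brightest were Dcn (0.08, SE 0.055) and Gsn (0.09, SE 0.068). That list had a mean change of 0.17 (camera adjusted p = 4.05e-09; adjusted p = 0.644 with an estimated correlation). Without both knockout sample 1 and wild type sample 4, chosen after seeing the data, the macrophage and fibroblast means were 0.12 and 0.11 (camera adjusted p = 0.000946 and 0.00108).

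Of 15 tendon genes, 13 had a lower mean in knockout, and 1 fell and 1 rose when adjusted over the list alone, with 0 over all genes. Chad, a cartilage and tendon matrix protein, fell by 0.45 (SE 0.10) and Cilp, another matrix protein, rose by 0.38 (SE 0.112), with limma adjusted p-values over the list alone of 0.0115 and 0.0431. The brightest members, Fmod and Thbs4, differed by -0.28 (SE 0.110 and 0.115 respectively). The list's mean change was -0.14 (camera adjusted p = 0.000220; adjusted p = 0.644 with an estimated correlation). It was -0.076 without knockout sample 1 and -0.080 without wild type sample 2 (camera adjusted p = 0.0166 and 0.0270). Of 17 Schwann cell genes, 1 fell when adjusted over the list alone and 0 over all genes: Ncmap, a protein of non-compact myelin, by 0.25 (SE 0.061, adjusted p = 0.0265 over the list alone in limma). The myelin genes Mbp, Mal, Drp2 and Pmp22 differed by -0.29, -0.25, -0.31 and -0.21, and Cnp by 0.06. Without wild type sample 2 the differences of Drp2 and Pmp22 were -0.15 and -0.05. The Schwann list's mean change was -0.12 (camera adjusted p = 0.00110; adjusted p = 0.644 with an estimated correlation), and it was -0.066 without wild type sample 2 (camera adjusted p = 0.0685) and -0.070 without knockout sample 1 (adjusted p = 0.0400).

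In all, camera called 7 of the 29 lists, 4 upward and 3 downward, and 0 calls held with an estimated correlation or by fry. At an unadjusted p under 0.05, 2 lists passed with an estimated correlation and 3 by fry. Camera called 12 lists without wild type sample 4 and 11 without knockout sample 3.

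**Figure D2:**
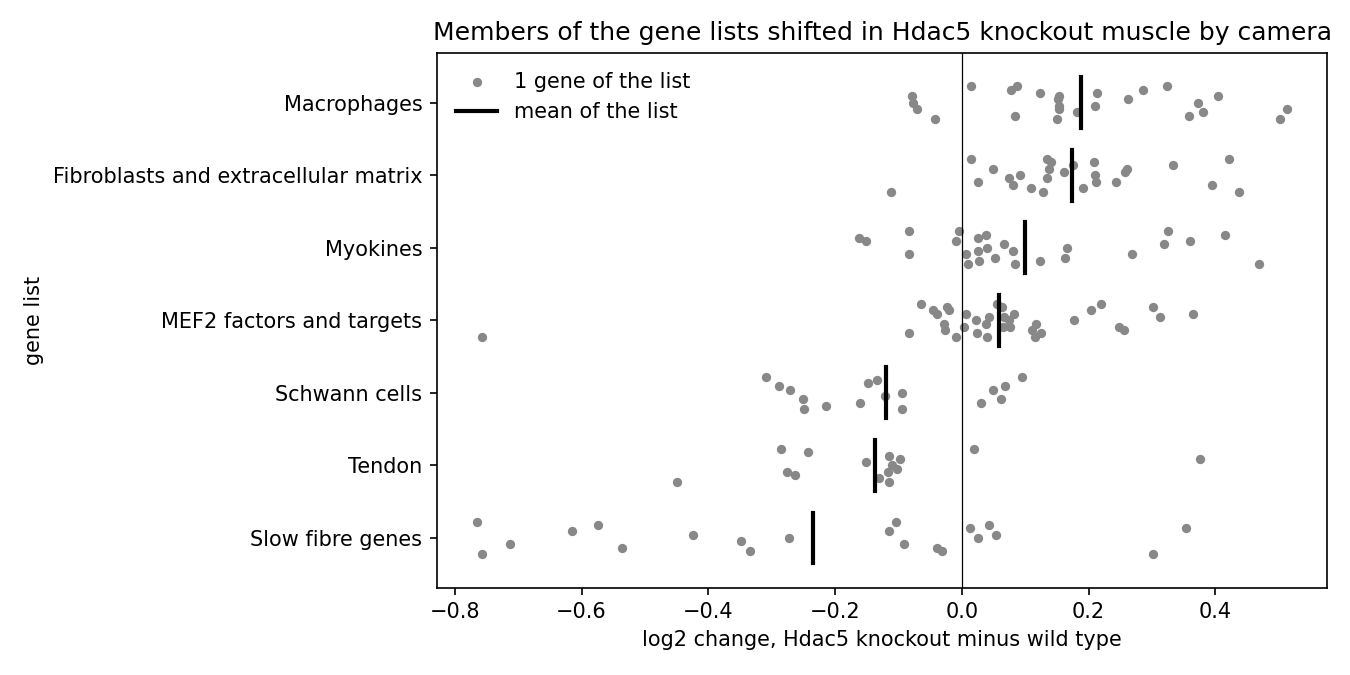
Log2 change (knockout minus wild type, horizontal axis) of each member (grey) of the 7 lists that camera called, with the mean of each list as a black bar. Slow fibre genes reach -0.76 while some members lie above 0, and macrophage and fibroblast members lie mostly above 0.

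Markers of other cell types did not pass as groups. Adipocyte markers had a mean change of 0.0077 (24 genes, camera adjusted p = 0.922). Agt, angiotensinogen, nonetheless rose by 0.38 (SE 0.068) when adjusted over the list alone (adjusted p = 0.00305, and 0.0763 over all genes, in limma). Plin4, Car3 and Fabp4 differed by 0.11, -0.06 and 0.05. Over 17 alternatives these ran from 0.05 to 0.17, from -0.10 to -0.02 and from 0.0001 to 0.13. Single samples decide the adipocyte list at the preset correlation. Without wild type sample 2 its mean was 0.17 (camera upward, adjusted p = 0.00179), and without wild type sample 3 it was -0.15 (camera downward, adjusted p = 0.0246). With an estimated correlation and all 8 samples its camera adjusted p was 0.954. Smooth muscle and pericyte markers had a mean of 0.013 and a median of -0.014 with a downward camera direction (15 genes, adjusted p = 0.922). When adjusted over that list alone, Acta2, smooth muscle actin, rose by 0.46 (SE 0.101) and the channel subunit Kcnj8 of pericytes fell by 0.46 (SE 0.093), each with a limma adjusted p of 0.00538, and 0 passed over all genes. The other named members, Abcc9 and Des, differed by -0.10 and -0.06. Endothelial markers had a mean of 0.0075 and a median of -0.0097 (23 genes, camera direction upward, adjusted p = 0.922), with Plvap at 0.20, Cd34 at 0.17 and the brightest, Cdh5, at -0.0048. Lymphocyte and neutrophil markers had a mean of -0.03 (19 genes, adjusted p = 0.289), with S100a8 at -0.14, Cd3g at 0.14, Cd79b at -0.07 and Ighm at -0.10 (0.06 as the mean of its probe sets). Satellite cell markers had a mean of -0.012 (16 genes, adjusted p = 0.679), with Myf5 at -0.12, Myf6 at -0.13 and Itga7 at 0.04, and that mean was -0.0030 without knockout sample 2 and -0.032 without knockout sample 4. In the endothelial, lymphocyte and satellite cell lists 0 members passed over all genes or when adjusted over the list alone. Of 5 red blood cell genes measured, Tfrc, the transferrin receptor, rose by 0.29 (SE 0.072) when adjusted over the list alone (adjusted p = 0.00780 in limma) and 0 over all genes. Bpgm differed by 0.12, and the list had a mean of 0.05 and a median of -0.03 (camera direction upward, adjusted p = 0.552). Without knockout sample 3 that mean was 0.033.

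The last 6 lists were not called with all 8 samples, and 0 of their members passed over all genes. Denervation and neuromuscular junction genes had a mean change of -0.04 (25 genes, camera adjusted p = 0.107), and Musk, the receptor kinase of the junction, fell by 0.41 (SE 0.090) when adjusted over the list alone (adjusted p = 0.0187 in limma); the acetylcholine receptor subunit Chrnb1 differed by -0.25. Immediate early genes split, with 2 that rose and 3 that fell when adjusted over the list alone, among the latter Ier3 at -0.27 and Fosl1 at -0.20. Their mean was 0.026 and their median -0.0027 (26 genes, camera direction upward, adjusted p = 0.923), and the mean was 0.0035 without wild type sample 4 and 0.012 without knockout sample 1, each with a downward camera direction. Interferon response genes had a mean of -0.05 (26 genes, adjusted p = 0.142), with B2m at -0.31 (SE 0.099) and Ifit3 at -0.21 (SE 0.065). Circadian clock genes had a mean of -0.03 (18 genes, adjusted p = 0.212), with Nfil3 at 0.26 and Dbp at -0.22. Protein breakdown and autophagy genes had a mean of 0.010 (32 genes, adjusted p = 0.922), with Klf15 at -0.22 and Map1lc3b at -0.16. Heat shock and unfolded protein genes had a mean of 0.0073 and a median of -0.0088 with a downward camera direction (27 genes, adjusted p = 0.932), with Hsp90b1 at 0.19 and Dnajb4 at 0.14. The denervation, clock and interferon lists each passed downward in 3 of 19 alternatives, but not with an estimated correlation (adjusted p = 0.644, 0.884 and 0.834). Without wild type sample 4 their camera adjusted p-values were 0.0313, 0.0340 and 0.0383, and without knockout sample 3 they were 0.0325, 0.0407 and 0.0425. The denervation list also passed under quantile normalization (0.0494), the interferon list without knockout sample 2 (0.0488), and the clock list without both knockout sample 1 and wild type sample 4 (0.0207), an alternative chosen after seeing the data. The denervation mean was -0.016 without knockout sample 1 (adjusted p = 0.462), the clock mean was -0.0013 without knockout sample 2, and the interferon mean was -0.017 without wild type sample 2. In the interferon, clock, protein breakdown and heat shock lists 0 members passed when adjusted over the list alone.

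All 8 samples showed a male pattern, with Xist at 6.12 in knockout and 6.07 in wild type and Eif2s3y at 10.89 and 10.76. Of the 4 sex-linked genes measured, 1 rose when adjusted over the list alone and 0 over all genes: Uty, a Y-linked demethylase, by 0.34 (SE 0.078, adjusted p = 0.00347 over the list alone and 0.192 over all genes in limma). Kdm5d differed by 0.020, a sign that turned under quantile normalization (-0.015).

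Genes next to Hdac5 on chromosome 11 were compared with genes elsewhere, and chance could not be excluded for the difference. Of the 200 neighbours, 11 (5.50%) had an unadjusted p under 0.01 in limma, against 440 of 19652 other genes (2.24%), an odds ratio of 2.54 (95% interval 1.24 to 4.70, Fisher's exact p = 0.00619). Of the 35 ways to split the 8 samples into 4 and 4, 3, the real one included, gave as large an odds ratio, and the highest of the others was 3.10. They included Fzd2, a Wnt receptor, at a difference of 0.44 (SE 0.070), Ccdc43 at -0.39 (SE 0.066), and Ace, angiotensin-converting enzyme, at 0.37 (SE 0.067), with limma adjusted p-values of 0.0535, 0.0739 and 0.0763. Cep112, Pitpnc1, Arf2, Rpl27, Axin2, Gna13 and Vps25 were also among the 11, with 1 unnamed gene model. The neighbours of Hdac5 were named after their values were seen. Of the changed genes, Abca5 and Utp18 lie on the same chromosome, with 110 and 263 tested genes between them and Hdac5. Elsewhere, Htra4 and Dusp26 both lie on chromosome 8, and Cmbl and C7 both on chromosome 15. The median size of change was 0.060 among the neighbours and 0.057 elsewhere. With 50 genes on each side the odds ratio was 2.28 (Fisher's exact p = 0.0777) and at an unadjusted p under 0.05 it was 1.45 (Fisher's exact p = 0.112). By the same exact test it was 1.52 without knockout sample 4 (p = 0.208), 2.10 without wild type sample 1 (p = 0.0633) and 1.87 without wild type sample 3 (p = 0.111). The other 7 of the 12 alternatives stayed past the threshold, with odds ratios from 2.28 without knockout sample 3 (Fisher's exact p = 0.0226) to 3.36 with dim probe sets left out (p = 2.58e-05).

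**Figure D3:**
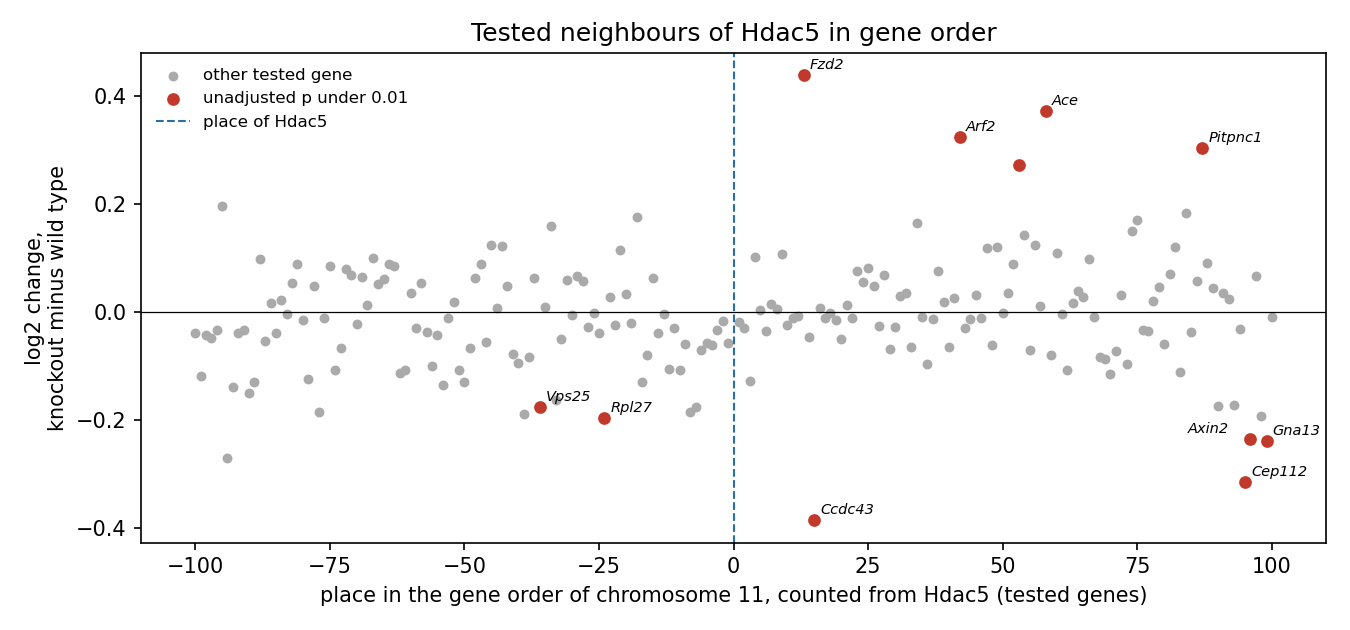
Log2 change (knockout minus wild type, vertical axis) of the 100 tested genes on each side of Hdac5, in gene order along chromosome 11 of assembly GRCm38.p6 (horizontal axis); red points are the 11 genes with an unadjusted p under 0.01. Of these, Fzd2 lies highest at 0.44 and Ccdc43 lowest at -0.39.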

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

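The tests of unnamed probe sets, of gene pairs along chromosomes, of the Prm1 gap between groups and of the heterogeneity of the cell type scores, and the use of the odds ratio near Hdac5 to weigh a linked segment, were chosen after the result was seen.

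Outside the named genes, 23 probe sets passed the threshold in limma over all probe sets, and each of the 23 was lower in every knockout sample than in any wild type sample. Their log2 changes ran from -3.79 to -0.59, with a median of -1.87. The most extreme, probe set 10339192, stood at 6.74 in knockout and 10.53 in wild type muscle, and probe set 10341765 at 6.62 and 10.28. All 23 belong to a block of 6617 probe sets that the platform annotation does not name. What these probe sets measure is not given in the sources used here. By comparison, 5 named probe sets passed over all probe sets. Of the 35 splits of the 8 samples into 4 and 4, 1, the real one, gave as many unnamed probe sets. The highest other split gave 2. A share of 1 in 35 is the smallest that this test can give, so chance is unlikely but not excluded.

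These probe sets and the genes near Hdac5 may each stem from donor-strain sequence, but a link between them was not tested. The unnamed probe sets were not placed along chromosomes. All 23 were lower in the knockout, while the neighbours of Hdac5 went both ways, with Fzd2 at 0.44 and Ccdc43 at -0.39. With every probe set past the adjusted threshold left out, the block's probe sets at an unadjusted p under 0.001 were compared with named ones. Of the block's, 71.0% were lower in the knockout (22 lower, 9 higher). Of the named ones, 33.96% were lower (18 lower, 35 higher, Fisher's exact p = 0.00146). Variants under the probes would give such a loss, although probe sets that share sequence are not independent. Since it is not known what the block measures, the comparison may not be of like with like. A shift of the whole block by the authors' normalization is argued against, because its median change was -0.0073. An effect of processing on the 23 probe sets alone was not tested. Near Hdac5 the odds ratio of 2.54 goes with a linked segment, but 2 of the 35 splits, the real one included, gave as many as 11 neighbours at an unadjusted p under 0.01 (highest other, 15) and 3 gave as large an odds ratio, so chance cannot be excluded there. For segments elsewhere, 16 pairs of the 100 genes of smallest p lay within 20 tested genes of each other. As many were given by 3.8% of 1000 random placements (median 10, 95th percentile 15) but by 14 of the 35 splits. Segments elsewhere therefore cannot be told apart from the ordinary clustering of co-varying genes. Of the changed genes, Prm1, Utp18, Abca5, H60b and Cmbl each lay in such a pair. H60b lay near lower gene models without a name on chromosome 10. Cmbl, which rose, lay near Ankrd33b (lower) and Cpq (higher) on chromosome 15. An effect of HDAC5 loss on these probe sets and genes stays open.

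Prm1, a gene of sperm heads, rose 3.93-fold in muscle. A spermatid programme switched on in the knockout is argued against, because 17 other spermatid genes, listed before the test, had a mean log2 change of -0.034 (SE over genes 0.016), and 0 of them had an unadjusted p under 0.05 in limma; Prm2 differed by -0.10 and Tnp2 by -0.01. A segment around Prm1 cannot be told apart, since 2 of its 164 neighbours had an unadjusted p under 0.01 (odds ratio 0.529, 95% interval 0.063 to 1.95, Fisher's exact p = 0.593), too few to decide. Prm1 sequence carried by the targeting construct cannot be told apart either: the gap of 1.71 between the lowest knockout and the highest wild type sample only restates the rise, and the make-up of the construct is not given in the sources used here. A direct effect of HDAC5 loss on Prm1 alone would look the same.

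Slow fibre, tendon and Schwann lists had lower means and macrophage and fibroblast lists higher means in the knockout. A lower share of muscle fibre RNA would raise all other types alike, provided that fibres do not express their markers. Of the 10 cell type scores 6 were higher and 4 lower. They did not move apart by more than their spread (heterogeneity statistic 15.1, exact permutation p = 0.143). The smooth muscle list holds Des, which is also among the MEF2 target genes of muscle, so such scores need not rise. The red blood cell score rests on 5 genes. A lower share of fibre RNA therefore cannot be told apart with these lists and 4 samples per group. The macrophage and fibroblast scores minus the tendon and Schwann scores differed by 0.31 (SE 0.105), but those lists were picked for their direction. Slow muscle, tendon and nerve carried along in unequal amounts at dissection may be the cause of the lower slow fibre, tendon and Schwann means. Within groups the slow fibre score followed the tendon and Schwann score (the only relation computed, Pearson r = 0.796, 2-sided permutation p = 0.0451, Spearman rho = 0.786, permutation p = 0.0503, 8 samples). The IL-6 cytokine, receptor and JAK-STAT score was highest in knockout sample 3 (9.18) and wild type sample 3 (9.24). It was lowest in knockout sample 1 (9.12) and wild type sample 1 (9.14). The slow fibre score was highest and lowest in those same samples. The relation with the tendon and Schwann score is therefore not shown to be particular to tendon and nerve. Without the 2 samples farthest from the median r was 0.455, so the relation rests on those. It says nothing on the higher macrophage and fibroblast means, where 25 of 26 fibroblast and matrix genes were higher. Slow and tendon transcripts are not scarce here, with Myh7 at 12.48 and Fmod at 11.42 in wild type muscle. A shift of fibre type with genotype stays open.

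Of the 35 splits, 1, the real one, gave as many as 13 changed genes (highest other, 2). The same held for the 8 genes higher (1 split, highest other 1) and the 5 genes lower (1 split, highest other 1), counting the larger direction of each other split. A share of 1 in 35 is the smallest that this test can give, so chance is unlikely for these counts but not excluded. The changed and the lower genes include Hdac5, the targeted gene. For the lists chance alone could give the count, since 16 of the 35 splits gave at least 7 shifted lists, and the highest other gave 13. At an unadjusted p under 0.05, 5 splits, the real one included, gave at least the 1576 genes of the real split. The highest gave 3298, which points to a structure of the samples other than genotype.

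Single samples lay far from the other 3 of their group, by Dixon's ratio at the 95% level, in 25 of 274 tests over 108 genes and 29 list scores, where chance marks about 1 in 20 (13.7). In knockout sample 1 this held for H60b (7.97), Lrrn1 (9.07), Mylk2 (12.70), Plin4 (10.56) and Dcn (13.85). In knockout sample 2 it held for Ramp1 (9.59), Cd34 (10.96) and Tfrc (11.78), in knockout sample 3 for Fosl1 (7.55), and in knockout sample 4 for Hdac5 (8.39), Cd3g (6.37) and the satellite cell score (8.69). In wild type sample 1 it held for Itga7 (9.92), and in wild type sample 4 for Esrrg (9.81). Wild type sample 2 stood apart 7 times, in Ctxn3 (10.90), Car3 (14.34), Fabp4 (12.03), Drp2 (8.58) and the myokine (9.11), macrophage (8.38) and Schwann cell (8.07) scores. Wild type sample 3 stood apart in Spinkl (7.53), Lrrn1 (10.40), Fosl1 (7.55) and Myf6 (12.22).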

How the results depend on the processing

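The omission of both knockout sample 1 and wild type sample 4 was chosen after seeing the data. Where a value differs below, the cause was not tested, except that fewer samples or fewer genes enter some fits. Of 1802 values of named genes under the alternatives, 1675 kept their direction and side of the threshold, 36 newly passed, 73 no longer passed and 18 reversed. Of 551 list values these numbers were 476, 22, 16 and 37. Most named genes had not passed with all 8 samples. Some alternatives leave each log2 change as it was, so direction could not reverse there. These were a trended and robust eBayes, the replicate block, the residual principal component and no moderation. An estimated correlation and fry likewise leave each list mean as it was. Hdac5 passed in all 17 alternatives (-1.52 to -1.46, highest adjusted p 0.000945), and Il6 in 0 of them (0.02 to 0.14, limma). Signal over background limits Il6 and other dim genes.

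Against 13 changed genes (8 higher, 5 lower), the counts were 36 (21 and 15) with dim probe sets left out, 44 (28 and 16) with a trended and robust eBayes, 31 (19 and 12) with array weights, 28 (2 and 26) over all probe sets, of which 23 were unnamed and 5 were among the 13 genes, 52 (36 and 16) with the first residual principal component as covariate, 4 (2 and 2) in the ordinary linear model, and 46 (30 and 16) at an adjusted p under 0.1. The residual component was taken from these same arrays after genotype was fitted. It removes residual spread without altering any log2 change, so its count of 52 may be too high. Under quantile normalization 13 genes were higher. With the replicate number as a block the counts were 30 (16 and 14), although the labels do not say that equal numbers pair the samples. Residuals of samples with equal numbers correlated at 0.34, -0.11, -0.15 and 0.34 for numbers 1 to 4. The counts were 5 (2 and 3) without both end samples. Leaving out 1 sample gave 5 to 20 changed genes (2 to 16 higher, 3 to 5 lower), 7 to 12 lists and odds ratios near Hdac5 of 1.52 to 3.29. The lists called were 0 with an estimated correlation and 0 by fry. The odds ratio was 2.28 with 50 genes on each side and 1.45 at an unadjusted p under 0.05. Sex as a covariate was not run because all arrays show 1 sex.

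The values that reversed had not passed to begin with. Quantile normalization gave -0.018 for Cd74, -0.0152 for Kdm5d, and list means of -0.0027 (IL-6 and STAT3 induced), -0.0007 (insulin), -0.0059 (protein breakdown), -0.0035 (heat shock), -0.0011 (adipocytes), -0.0189 (endothelial) and -0.0020 (smooth muscle). Median centring gave -0.0017 (IL-6 and STAT3 induced), -0.0006 (fast fibre) and -0.0001 (heat shock). Array weights gave -0.1061 for Cd74, 0.0301 for Cdh5, -0.0170 for Kdm5d, -0.0009 (IL-6 and STAT3 induced) and -0.0134 (adipocytes). The mean of the probe sets gave 0.0633 for Ighm. Without both end samples the means were -0.0029 (insulin), -0.0037 (fast fibre), -0.0227 (protein breakdown), -0.0105 (immediate early) and 0.0328 (lymphocytes).

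With 1 sample left out, the ranges of reversed results were -0.1180 to 0.2003 for Cd74, -0.0249 to 0.0520 for Kdm5d, -0.0499 to 0.0770 for Cdh5, -0.1557 to 0.0123 for Cd79b and -0.0191 to 0.1149 for Xist. For list means they were -0.0087 to 0.0245 (IL-6 and STAT3 induced), -0.0092 to 0.0313 (protein breakdown), -0.0056 to 0.0188 (heat shock), -0.1480 to 0.1710 (adipocytes), -0.0266 to 0.0513 (endothelial), -0.0174 to 0.0427 (smooth muscle), -0.0046 to 0.0205 (fast fibre), -0.0676 to 0.0019 (lymphocytes) and -0.0348 to 0.0073 (mitochondrial biogenesis). Both ends of the adipocyte range passed in camera at the preset correlation, 0.1710 without wild type sample 2 (adjusted p = 0.00179) and -0.1480 without wild type sample 3 (adjusted p = 0.0246).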
